A study of Mus musculus with 6 samples.

How the data were processed

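Small-intestinal enteroids, which are organoids grown from intestinal crypts, came from C57BL/6J mice. Per the labels' protocols they were differentiated for 4 days, and the treated wells then received recombinant mouse IL-22 for 24 hours. The labels give the dose as 2 ng/ml, whereas the header of the authors' deposited table names the treated condition with 100 ng, and the dose is therefore unsettled. The labels also give the age of the mice as 6 weeks in one place and as 8 weeks, or 7 days for neonates, in the protocol. Polyadenylated RNA was made into libraries with 15 PCR cycles and sequenced as single reads, per the labels' protocols. There were 6 libraries, each from 1 well: 4 untreated control wells from 2 mice and 2 IL-22 wells from 1 mouse. The labels call wells of a mouse technical replicates and do not say whether mouse 1 of both groups was the same animal.

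The data were the authors' deposited table of 690 genes that they had selected as different. The submitters' processing notes name BWA 0.5.9 and Picard 1.58, and the genome build, the annotation and the counting program are not given in the sources used here. The group means in the authors' deposited table are in RPM (reads of a gene per 1000000 reads of the library), which was inferred from the values because no header names the unit, and a library with no read of a gene carried the value of 1 read. The table also gives the standard error of each mean (SEM) and the mean number of raw reads. The deposited fold or ratio is the IL-22 mean over the control mean. The authors' p-values were recomputed from the means and SEMs as a pooled-variance comparison of untransformed values with 4 degrees of freedom, to a largest difference of 1.07e-06. The authors' adjusted p-values equal a Benjamini-Hochberg adjustment over the 690 listed genes alone. Each listed gene differed at least 2-fold, had a p-value of at most 0.0239 and had a mean of at least 20 reads in the group where it was higher. Genes absent from the list were not analysed here, so absence does not show that a gene was unchanged. Values of single control wells were not used here. Whether counting used the strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

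Some consequences follow from that selection. The adjusted values would stay under 0.05 for all listed genes only in a family of up to 1442 genes, whereas GENCODE M21 holds 21951 protein-coding genes. Adjustment over all protein-coding genes gave each unlisted gene the largest possible p-value, because their p-values are unknown. Values adjusted in this way are upper bounds, and counts of genes that pass are lower bounds. With 4 and 2 wells, any p-value under 0.0612 forces both IL-22 libraries beyond all control libraries, so that this separation, found in 690 of 690 genes, adds no evidence (chance alone gives 13.3% without selection). The smallest p that an exact permutation of these wells can give is 0.0667. The p-values measure the spread between wells, with 1 treated mouse, and not the spread between treated animals.

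Depth was recovered from rows with few reads, in which values are whole multiples of what 1 read is worth. Both IL-22 values of a gene follow from its mean and SEM and were assigned to the deeper or the shallower library. In 593 of 593 genes with under 2000 mean reads, both values came out within 0.01 of a whole read. For the controls, 7 of 7 low rows were reproduced, which gives depths but no values per well. The IL-22 libraries held 32500000 and 29900000 reads and the controls 36600000, 35200000, 27400000 and 22600000, and 3 reads correspond to 0.082 to 0.132 RPM in a control library. Counting intervals of folds (95%, exact conditional binomial) used these totals and cover counting error only, since PCR reads are not independent molecules. They refer to the count ratio, which is the summed IL-22 reads per total depth over the same for controls. The count ratio leaves out the value of 1 read given to empty libraries and can differ from the deposited ratio.

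Standard errors of log2 fold changes were propagated from the authors' SEMs. Gene names were matched by Entrez identifier to RefSeq genes of GRCm38.p6 (679 of 690 matched), and no coordinates are printed because no build is named. The share of each gene's 31-base words found in no other gene was computed from GENCODE M21. Before the data were examined, 27 gene lists and a rule for named genes were fixed. That rule took the 15 higher and 15 lower genes with the largest change among those with an adjusted p under 0.05, a mean of at least 5 RPM in the higher group, a symbol that is not a gene model, and separated libraries, then 6 genes of the IL-22 pathway, then up to 4 genes of each list by adjusted p. Some genes that this rule names are not reported here. The planned limma-trend and camera tests need values per well and were not run, nor was the planned comparison of the control mice. In their place, the authors' p-values were used for genes, and for lists with at least 5 listed members Fisher's exact test (two-sided) compared higher and lower counts with those of the other listed genes. Benjamini-Hochberg adjustment ran over the 8 lists tested. This test concerns direction among listed genes, is not an enrichment against the genome, and treats genes as independent. Alternatives covered filters, fold thresholds, pseudocounts, the family of the adjustment, unequal variances, the log2 scale and leaving out libraries.

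The procedures were tested on simulated data for the IL-22 comparison with 690 genes, of which 200 were changed. A first version of the depth search missed the simulated IL-22 depths and was replaced. The final version recovered them to within 3.51e-06% and the control depths to within 0.0038%. At 2.5-fold, 28 of 33 higher and 25 of 34 lower genes were called, at 4-fold 34 of 34 and 25 of 33, and at 10-fold 33 of 33 and 29 of 33, so that simulated lower genes were missed more often. Of the unchanged genes, 1 of 490 was called. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.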

Results

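Gene expression was measured by RNA-seq in mouse small-intestinal enteroids that were left untreated or were treated with IL-22, a cytokine that acts on epithelial cells through STAT3. The series asked what IL-22 does in the epithelium of the newborn gut, and the libraries analysed here came from mice without necrotizing enterocolitis. There were 4 control libraries from 2 mice and 2 IL-22 libraries from 1 mouse, with 22600000 to 36600000 reads each. The IL-22 dose is 2 ng/ml in the labels and 100 ng in the header of the authors' deposited table. Values are the authors' group means ± SEM in RPM (reads of a gene per 1000000 reads of the library), and only the 690 genes that the authors listed as different could be examined.

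With IL-22, the antimicrobial lectin genes Reg3g and Reg3b stood at the highest levels of any listed gene. In the authors' deposited table, Reg3b (Entrez 18489, chromosome 6) was at 130.3 ± 26.2 RPM in controls and 26048 ± 50.0 RPM with IL-22, and Reg3g (Entrez 19695, chromosome 6) went from 33.8 ± 2.46 to 19413 ± 70.4 RPM. Together both genes held 4.55% of the reads with IL-22 and 0.0164% of those in controls. The transcript of Lct, which encodes the lactose-digesting enzyme lactase, fell. Lct (Entrez 226413, chromosome 1) was 13.1-fold lower in the authors' deposited table, at 31.3 ± 2.34 RPM in controls and 2.39 ± 0.0191 RPM with IL-22. Of the 690 listed genes, 267 were higher and 423 were lower with IL-22. The median change was 3.15-fold among higher genes and 2.70-fold among lower genes. At a threshold of 4-fold, 91 genes were higher and 95 lower.

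**Figure D1:**
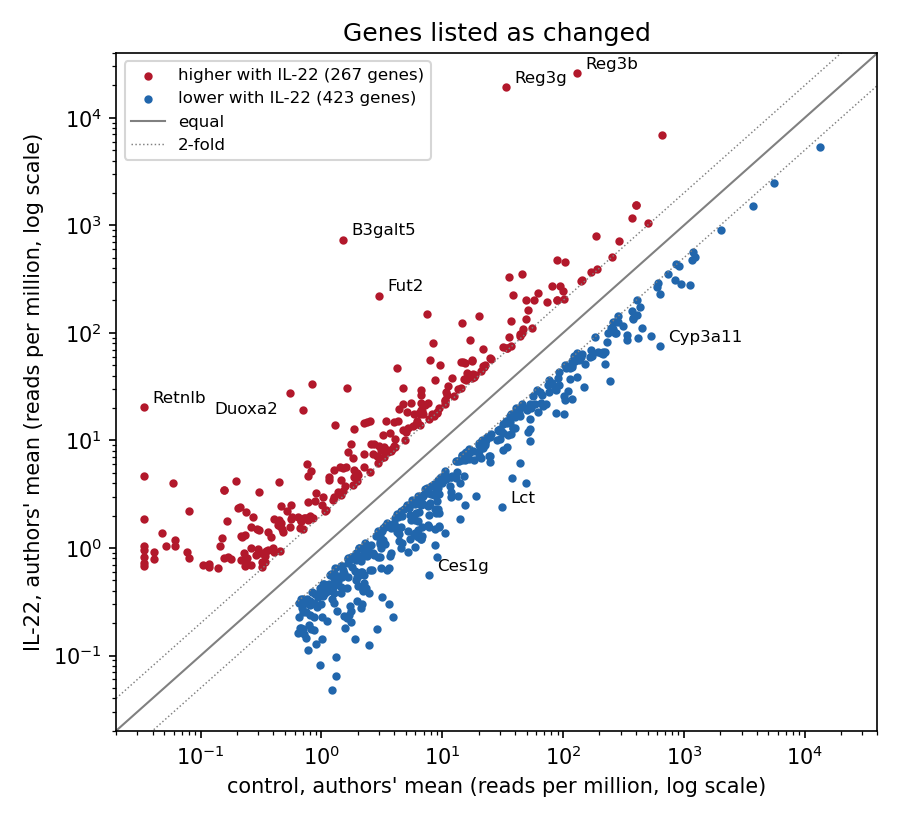
Authors' group means of the 690 listed genes, control on the horizontal axis and IL-22 on the vertical axis, both in RPM on log scales. Each point is a gene, red for the 267 higher and blue for the 423 lower with IL-22, and the dotted lines mark 2-fold differences. Reg3b, Reg3g, B3galt5, Fut2 and Retnlb lie farthest above the line of equality among the labelled genes.

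Several of the most increased genes act on glycans or on the mucosal surface. B3galt5 (Entrez 93961, chromosome 16), a galactosyltransferase, was 488.0-fold higher in the authors' deposited table, at 1.51 ± 0.0879 RPM in controls and 736.8 ± 49.6 RPM with IL-22. Fut2 (Entrez 14344, chromosome 7), the fucosyltransferase that fucosylates the epithelial surface, was 74.6-fold higher, and Mgat4c was 20.1-fold higher in the same authors' deposited table. Dmbt1, a secreted scavenger receptor, rose from 652.8 ± 8.19 to 6949 ± 725 RPM in the authors' deposited table. Retnlb (Entrez 57263, chromosome 16), which encodes the antibacterial protein RELMβ, reached 20.5 ± 1.52 RPM with IL-22 in the authors' deposited table. It had 1 read in all controls together, so that its count ratio had a 95% counting interval of 446 to 98306. Duoxa2 and Duox2, which encode the maturation factor and the oxidase that release hydrogen peroxide at the cell surface, were 50.4-fold and 40.2-fold higher in the authors' deposited table. Nos2, the inducible nitric oxide synthase, was 10.7-fold higher there, and the kinase gene Ptk6 was 27.3-fold higher. Ly6a, Ppef1, Socs3 and Tifa were 19.1-fold, 11.3-fold, 9.64-fold and 9.13-fold higher in the authors' deposited table. Of the sequence of Ly6a, 68.1% is found in no other gene. Over the 15 genes with the largest increases among those with at least 5 RPM in the IL-22 mean, the authors' adjusted p was at most 0.00464. With the authors' p-values adjusted over all protein-coding genes, Duox2, Nos2 and Socs3 of these 15 did not stay under 0.05. Genes with an IL-22 mean under 5 RPM, such as Lrg1 and Lcn2, were left out of the 15. Lrg1 had 1 read and Lcn2 6 reads in all controls, with 95% counting intervals of 103 to 22858 and 37.1 to 225.0 for their count ratios, and the authors' adjusted p was 0.0144 and 0.00889.

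Among genes with at least 5 RPM in controls, those with the largest decreases were mainly enzymes and transporters. Ces1g (Entrez 12623, chromosome 8), a carboxylesterase, was 13.8-fold lower in the authors' deposited table, from 7.74 ± 0.875 to 0.562 ± 0.0073 RPM. Slc5a4b, a sodium/glucose cotransporter family member, was 12.1-fold lower in the authors' deposited table. Cyp3a11, a drug-metabolizing cytochrome P450, fell from 630.5 ± 66.2 to 75.1 ± 0.474 RPM in the authors' deposited table. Cyp3a41a, Cyp3a41b and Cyp3a44 were 8.21-fold, 10.9-fold and 7.53-fold lower there, but only 0.148%, 4.13% and 51.6% of their sequence is found in no other gene, and their reads cannot be told apart with certainty from those of their relatives. Cyp2c38, Ces2a and Cyp2d34 were 7.02-fold, 6.82-fold and 6.18-fold lower in the authors' deposited table. The transporter genes Slc14a1 and Slc47a1 and the genes Mylk3 and Cd83 were 6.13-fold, 5.92-fold, 8.41-fold and 5.91-fold lower there. The authors' adjusted p was at most 0.0123 over these 15 genes with the largest decreases. With the authors' p-values adjusted over all protein-coding genes, only Cyp2d34 and Slc14a1 of the 15 stayed under 0.05. Lct was then at 0.101, Cyp3a11 at 0.24 and Ces1g at 0.252. These values are upper bounds, because each unlisted gene was given the largest possible p-value.

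**Figure D2:**
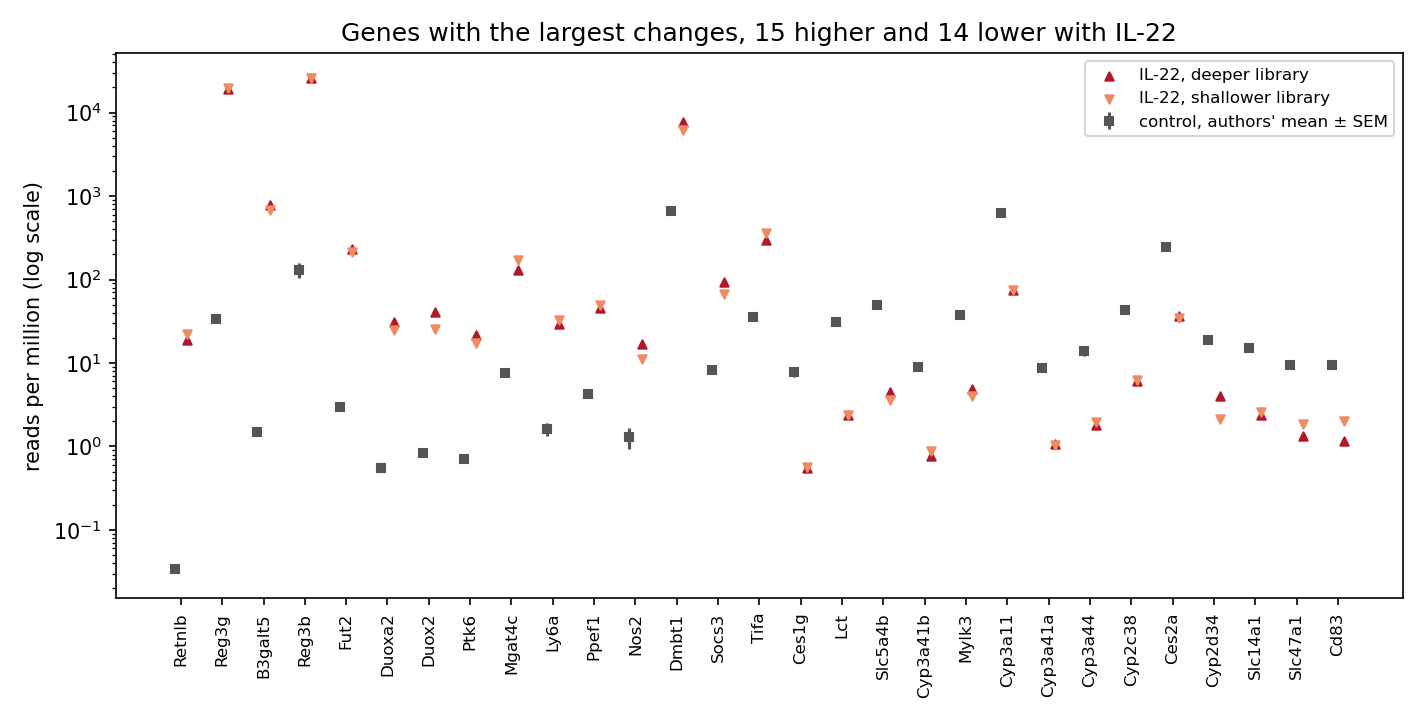
The 15 higher and 14 of the 15 lower genes with the largest changes among those with at least 5 RPM in the higher group, in RPM on a log scale. Squares are the authors' control means with their SEM, and triangles are both IL-22 libraries as recovered from the authors' mean and SEM. Both IL-22 libraries lie on the same side of the control mean for each gene, which the authors' selection by p-value forces.

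Among the lists fixed before the data were examined, the IL-22 and STAT3 response stood out. Of its 24 genes, 16 were listed, with 15 higher and 1 lower, and the direction differed from that of the other listed genes (Fisher's exact test, adjusted p = 4.24e-05 over 8 lists). Besides the genes above, Il18 was 5.13-fold and Stat3 itself 2.54-fold higher in the authors' deposited table, the latter from 35.7 ± 1.33 to 90.9 ± 7.26 RPM. Reg3a, a relative of Reg3b, went the other way, from 258.7 ± 11.5 to 108.8 ± 1.05 RPM in the authors' deposited table. Il22ra1 and Il10rb, which encode the receptor chains, were not among the listed genes. Adjusted over the list alone, 16 of 16 passed, which the authors' selection forces. Adjusted over all protein-coding genes, 6 of the 16 passed, and the direction call of the list was lost with that adjustment and with unequal variances.

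Of the 31 absorptive enterocyte genes, 11 were listed and 20 were not, and 11 of the 11 were lower (Fisher's exact test, adjusted p = 0.0173). In the authors' deposited table, Fabp2, a fatty acid-binding protein gene, fell from 841.1 ± 48.5 to 309.7 ± 8.74 RPM. Treh, which encodes trehalase, was 3.07-fold lower there. In the list of xenobiotic and bile acid handling, 9 of 23 genes were listed and 9 were lower (Fisher's exact test, adjusted p = 0.0234). Gstm3, Abcb1a and Abcc2, a glutathione transferase and a pair of efflux pumps, were 3.94-fold, 3.36-fold and 2.12-fold lower in the authors' deposited table. Of their sequence, 62.3%, 76.7% and 99.8% is found in no other gene. Adjusted over the list alone, 11 of 11 enterocyte and 9 of 9 xenobiotic genes passed, which the authors' selection forces. Adjusted over all protein-coding genes, 0 and 3 passed. The direction calls of both lists were lost with unequal variances, and that of the xenobiotic list also on the log2 scale.

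Among regenerative and fetal-like epithelial genes, 5 of 18 were listed and 5 were higher (Fisher's exact test, adjusted p = 0.0173). In the authors' deposited table, Anxa1 rose 5.22-fold, from 1.77 ± 0.126 to 9.23 ± 0.447 RPM, Il33 rose 4.08-fold and Anxa3 2.52-fold. Of 21 glycolysis and hypoxia genes, 5 were listed and 5 were higher (Fisher's exact test, adjusted p = 0.0173), including the hexokinase genes Hk2 and Hk1, which were 2.16-fold and 2.22-fold higher in the authors' deposited table. This last list kept fewer than 5 listed members without either IL-22 library, on the log2 scale and in the worst case for a control library. It was therefore not tested in these settings. For the same reason the regenerative list was not tested with at least 100 reads in the higher group and with 1 RPM added. Neither list was tested with 5 RPM added or with unequal variances. Adjusted over all protein-coding genes, 2 regenerative and 0 glycolytic genes passed.

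The other tested lists held genes of both directions and did not pass the direction test. Fatty acid oxidation and PPAR targets had 6 lower genes and 1 higher gene, and retinoid metabolism also had 6 lower and 1 higher (Fisher's exact test, adjusted p = 0.258 for each). Ppara, the lipid-sensing receptor gene, was 2.12-fold lower in the authors' deposited table, Angptl4 was 4.12-fold lower, and the acyl-CoA dehydrogenase gene Acadl was 2.14-fold higher. Adh1, an alcohol dehydrogenase gene, fell from 1116 ± 65.5 to 276.0 ± 55.8 RPM, and Retsat and Dhrs3 were 2.51-fold and 2.91-fold lower in the authors' deposited table. Isx, a transcriptional repressor of retinoid genes in the intestine, was the higher retinoid gene, with 1 read in all controls and a 95% counting interval of 15.0 to 3551 for its count ratio. The list of oxidative stress and NADPH oxidase had 4 higher and 2 lower genes (Fisher's exact test, adjusted p = 0.258), with catalase (Cat) 2.77-fold and Nqo1 2.30-fold lower in the authors' deposited table.

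**Figure D3:**
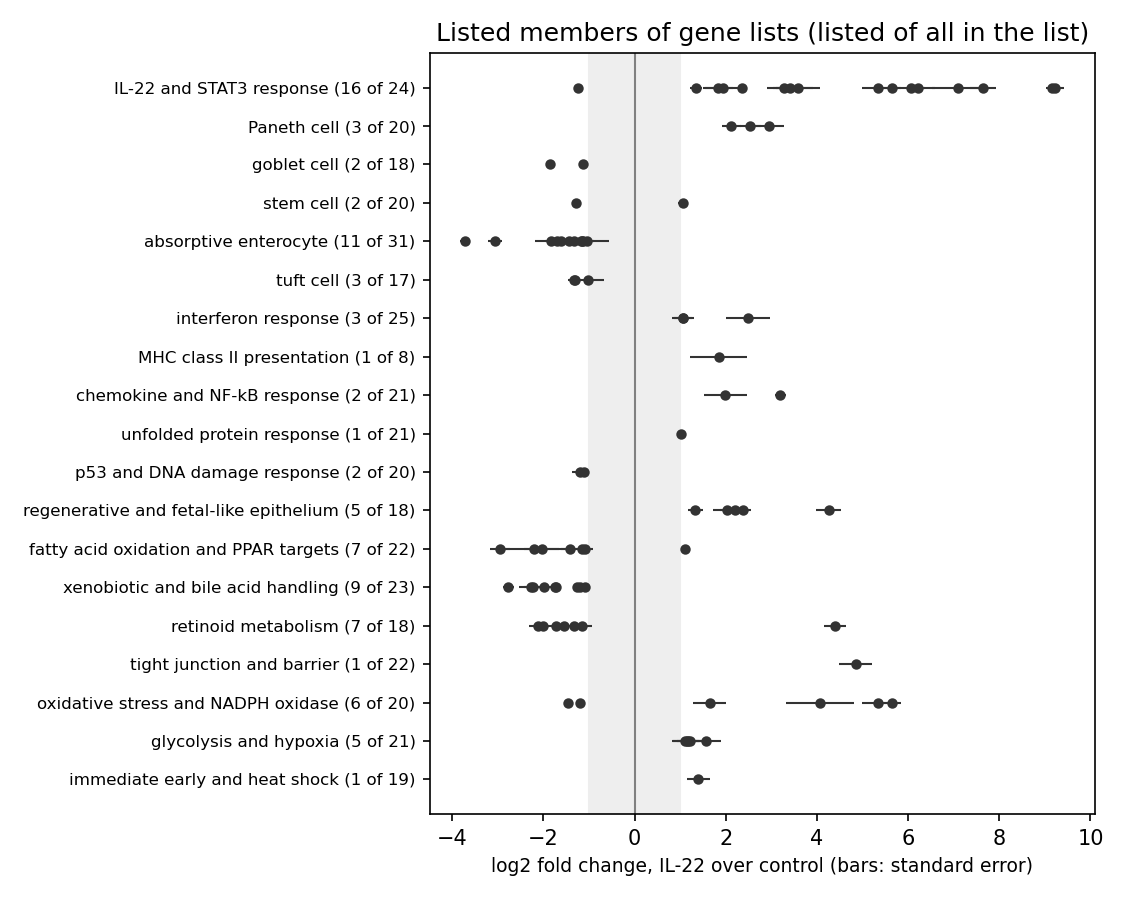
Log2 fold changes, IL-22 over control, of the listed members of each list that had any, with the standard error propagated from the authors' SEMs. The grey band marks changes under 2-fold, which the authors' list leaves out. The listed members of the enterocyte list lie to the left of 0 and 15 of 16 of the IL-22 and STAT3 list to the right.

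Markers of single epithelial lineages were listed in small numbers and were not tested as lists. The Paneth cell genes Mmp7, Mptx2 and Pla2g2a were 5.82-fold, 7.76-fold and 4.36-fold higher in the authors' deposited table, with 17 of the 20 genes of that list not listed. The goblet cell gene Bcas1 was 3.62-fold lower and Klk1 fell by 1.13 on the log2 scale, and the tuft cell genes Pou2f3, Ptgs1 and Trpm5 were 2.52-fold, 2.49-fold and 2.02-fold lower in the authors' deposited table. Of the stem cell genes, Olfm4 fell from 3703 ± 145 to 1525 ± 67.5 RPM and Prom1 rose from 189.4 ± 5.17 to 394 ± 24.2 RPM in the authors' deposited table. The interferon response genes Zbp1, Irf1 and Oasl2 were 5.61-fold, 2.08-fold and 2.07-fold higher, and H2-Ab1 of the MHC class II list was 3.58-fold higher in the authors' deposited table. Zbp1 and H2-Ab1 had low levels, from 0.118 to 0.661 RPM and from 0.450 to 1.61 RPM. In these lists, 22 of the 25 interferon and 7 of the 8 MHC class II genes were not listed. Of the chemokine and NF-kB list, Icam1 and Cxcl1 were 9.13-fold and 3.97-fold higher in the authors' deposited table, with 19 of its 21 genes not listed. Cxcl1 was low, from 0.228 to 0.906 RPM. Muc1 was the listed gene of the tight junction and barrier list, at 28.8-fold higher in the authors' deposited table, and had 4 reads in all controls. Xbp1 of the unfolded protein response was 2.01-fold higher, and Plk2 and Trp53inp1 of the p53 list were 2.15-fold and 2.28-fold lower in the authors' deposited table. Ier3 was 2.63-fold higher among the immediate early and heat shock genes in the authors' deposited table.

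No gene was listed from 8 of the 27 lists: proliferation, enteroendocrine cell, Wnt and Notch pathway, cholesterol synthesis, mitochondrially encoded, haematopoietic cell, mesenchymal and muscle cell, and endothelial and neural cell. The last 3 of these hold 51 marker genes of other cell types. Not being listed does not show that these genes were unchanged. The p-values compare wells, with 1 treated mouse, and 149 of the 690 genes passed when the authors' p-values were adjusted over all 21951 protein-coding genes. That adjustment gave each unlisted gene the largest possible p-value, so 149 is a lower bound. Of those 149 genes, 94 were higher and 55 lower. Of the genes named above, Cyp3a44, Ptgs1, Pou2f3 and H2-Ab1 lost the call without either IL-22 library, Oasl2 without the shallower and Hk1 without the deeper. These calls give the lone IL-22 library the spread of the controls. A strongly raised gene can then hardly lose its call, so a call that was kept is not evidence of robustness.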

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

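The 2-fold threshold, the filter of 10 reads and leaving out each IL-22 library were chosen before the data were examined, and the other alternatives, the worst case for a control library included, after the data were seen. The 690 listed genes became 186 at a 4-fold threshold, 149 with adjustment over all protein-coding genes, 16 with Bonferroni adjustment over the same genes, 431 when 1 RPM was added to both means and 224 when 5 RPM was added. The share of lower genes, 61.3% in the list, was 51.1% at 4-fold, 36.9% with adjustment over all protein-coding genes and 12.5% with Bonferroni adjustment. Unequal variances left 490 genes, 75.1% of them lower. In the deeper IL-22 library taken alone, 600 genes were at least 2-fold from the control mean, in the shallower 641, and in both 551. Calls without an IL-22 library assumed that the lone library varies as the controls do. Strongly raised genes can hardly fail under that assumption, so calls that were kept show little. Leaving out any control library in the worst case that the SEMs allow left 592 genes at 2-fold, without a test. The log2 scale left 675 genes, and 589 had 10 mean reads in each group. Of the 5 lists with a direction, 1 was left at 4-fold, 0 with adjustment over all protein-coding genes, 0 with Bonferroni adjustment and 0 with unequal variances, where 1, 1, 0 and 5 lists had enough members left to test. On the log2 scale 3 were left, without the xenobiotic and glycolysis lists, and 3 with 5 RPM added, without the regenerative and glycolysis lists. The regenerative list, and the glycolysis list in both settings, had fewer than 5 listed members left and were not tested. The list left at 4-fold was the IL-22 and STAT3 response. The cause was not tested further. For the 76 named genes, 45 lost the call with adjustment over all protein-coding genes, 1 on the log2 scale (H2-Ab1), 5 without the deeper and 5 without the shallower IL-22 library. No paired analysis was possible because the table holds group means and its control values carry no mouse or well. For the same reason the planned count models, other normalizations, fits within a mouse, sums per mouse, tests against a fold threshold and the comparison of the control mice were not run. Low depth limits genes with few control reads, for which the ratio has a wide counting interval.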

Other observations

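The gene families, the annotation terms and the tests of the excess of lower genes and of the enzyme families were chosen after the data were seen. The tests of the 10-fold genes were written before their results were seen. Among the genes in the authors' deposited table, 7 genes picked by name as builders of glycan chains, after they were seen, were higher, and unlisted genes of that kind were not analysed here. Glycosyltransferases as a whole went both ways, since 6 of 6 UDP-glucuronosyltransferase genes were lower, and the authors' term for transfer of hexosyl groups had 7 higher and 4 lower genes (Fisher's exact test, adjusted p = 0.282 over 677 terms). The 7 genes include Gcnt3, from 80.6 ± 2.85 to 274.2 ± 1.89 RPM, B4galt1, from 101.7 ± 0.976 to 208.1 ± 1.54 RPM, and Fut1, 2.96-fold higher. Among the annotation terms that the authors' deposited table attaches to its genes, immune system process had 41 higher and 13 lower genes (Fisher's exact test, adjusted p = 4.89e-06 over 677 terms). Oxidation-reduction process had 13 higher and 73 lower genes (Fisher's exact test, adjusted p = 0.000126). Fatty acid metabolic process had 3 higher and 23 lower genes (Fisher's exact test, adjusted p = 0.026). Retinoid metabolic process had 0 higher and 10 lower genes (Fisher's exact test, adjusted p = 0.0459), whereas the fixed lists on these themes did not pass. Reg1 and Reg4, relatives of Reg3b, were lower in the authors' deposited table, Reg1 from 532.9 ± 41.2 to 93.1 ± 0.69 RPM, whereas Reg3d was higher there, from 1.25 ± 0.0998 to 2.82 ± 0.0432 RPM. The rows of H19 and Mir675 hold identical values, and since Mir675 lies within H19 they count as 1 set of reads.

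More listed genes were lower than higher. A first hypothesis is that reads taken up by Reg3b and Reg3g lowered the share of the other genes. Leaving both genes out of the totals raised the IL-22 values 1.05-fold, and an initial form of this test, with a bound of 90%, left 377 of 423 lower genes (89.1%) at or below 0.5 of control and did not decide. It was replaced because unlisted genes could enter on the higher side. At a 2.2-fold threshold, above which none can enter, 54.9% were lower, with a lower 95% limit of 50.7% that assumes independent genes. From a threshold of 2.1 to 1 of 4, lower genes made up 60.3% down to 51.1% of the changed genes before rescaling and 55.7% down to 46.4% after it, so the fall with the threshold is not evidence on read uptake. At 2.5-fold, the lower 95% limit went from 53.2% to 49.0% with rescaling, while at 2.1-fold and 2.2-fold it stayed above 50%. Read uptake and a real excess therefore cannot be told apart with these genes. The excess also depends on the selection. With adjustment over all protein-coding genes 94 genes were higher and 55 lower, and with Bonferroni adjustment 14 and 2. With unequal variances, 122 were higher and 368 lower. Simulated lower genes were missed more often by the pooled-variance comparison. Some of them had almost no control reads, unlike the listed lower genes, so the simulation does not measure what the comparison does to the latter. The selections differ in direction and do not decide whether the excess is real. A lower share of enterocytes that reduced all their genes by 1 factor stays open too. The log2 fold changes of the 11 listed enterocyte genes had a standard deviation of 0.86 against a median standard error of 0.15, but that spread rests on Lct and Cyp3a11, and without them it was 0.28 against 0.15 over 9 genes.

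There were 36 sets of reads at least 10-fold higher, with H19 and Mir675 counted once. Few control reads may inflate such ratios, but for 27 of the 36 the count ratio kept a lower 95% counting limit of 10 or more, among them 9 of the 9 with 3 or fewer control reads. For the other 9, counting error does not exclude a ratio under 10, in part because the ratio lies close to 10, as for Nos2 with 151 control reads. A single IL-22 library could also raise such ratios. In the lower of the IL-22 libraries, 29 of the 36 were at least 10-fold above the control mean, and the smallest such ratio was 7.11. The authors' selection by p-value limits the spread between both IL-22 wells and so forces this outcome for the larger ratios. The count is therefore not separate evidence against a single library. A difference between the treated mouse and the control mice stays open and was not tested.

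The cytochrome P450, carboxylesterase, glutathione S-transferase and UDP-glucuronosyltransferase families were lower in 54 of 56 listed genes (Fisher's exact test, adjusted p = 2.98e-09 over 11 family tests), with a median 3.47-fold decrease, although the families were pooled after they were seen to fall and relatives that share reads are counted more than once in that p. Taken singly, the adjusted p was 0.00124 for cytochrome P450, 0.019 for carboxylesterase and for glutathione S-transferase, and 0.12 for UDP-glucuronosyltransferase, which did not pass (Fisher's exact test). Reads shared between near-identical genes could move relatives together. Of the members with at least 90% of their sequence found in no other gene, 20 of the 20 were lower. With 54 of the 56 listed genes lower, a mostly lower count was fixed in advance. It shows only that the listed decreases were not confined to genes that share much sequence. A decrease of these families with IL-22 remains a hypothesis, because a lower share of mature enterocytes and a difference between mice stay open for them.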
